A study of Mus musculus with 46 samples.

How the data were processed

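RNA from the liver of 46 mice was measured on Affymetrix mouse whole-transcript arrays, 1 array per mouse, in 8 groups formed by 2 experiments (virgin and pregnant mice) and 4 arms (untreated, formulation, micro ZnO, nano ZnO). The deposited values are log2 intensities that the authors made with RMA, that is background correction, quantile normalization and summarization of probes into probe sets, per the submitters' processing notes, which give no software version. The values were checked to lie on a log2 scale, and array medians lay apart between the 2 experiments, which was read as separate normalization although the notes do not state it. All 46 columns of values were used and 0 were left out. The values used came without detection calls or scan dates, and the number of arrays limits the precision.

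The table held 35512 probe sets. Of these 21789 had 1 gene symbol, 1621 had several and 12102 had none, and the 23410 with a symbol, which stand for 19939 genes, were tested. Entrez identifiers of 21698 probe sets matched a mouse gene table of the assembly GRCm38.p6, used for names alone. No symbol changed on this update (0), and 91 probe sets kept the symbol of the platform. No genome coordinates were used.

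Within each experiment a linear model with the 4 arms was fitted in R 4.3.3 with limma 3.58.1, with its empirical Bayes moderation of variances. From it came each sunscreen arm minus untreated, each particle arm minus formulation and nano ZnO minus micro ZnO. A joint model with the 8 groups gave the interaction tests, the response of pregnant mice minus that of virgin mice, and the difference of the untreated groups. Benjamini-Hochberg adjustment ran over the 23410 probe sets of each comparison, tests were two-sided, and a probe set was called at an adjusted p under 0.05. A value after ± is the SE of a log2 change unless SD is named. Groups of values that are not gene tests were compared with two-sided exact permutation tests.

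Gene lists numbered 42 and covered zinc handling, liver metabolism, hormone and stress responses, inflammation and markers of the other cell types of liver. With at least 3 measured members required, 41 were tested. Camera, which compares a list with all other genes, ran on 1 probe set per gene with its preset correlation of 0.01 and once more with a correlation estimated from the data. Fry, which asks whether the genes of a list move on balance one way, ran beside it. Adjusted p values of lists are over the 41 lists. Some lists share members, as Mt1, Mt2 and Lcn2 stand among both acute-phase and glucocorticoid-responsive genes and Lcn2 also stands among neutrophil markers.

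The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among called genes of a comparison (12 each way for pregnant minus virgin), the 3 smallest p values where none was called, 6 zinc genes always (Mt1, Mt2, Slc30a1, Slc30a10, Slc39a4 and Slc39a14) and up to 4 members of each list described. The text prints only part of the genes so selected. A gene with several probe sets is represented by the one with the highest mean.

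Alternatives were dim probe sets left out (below the 40th percentile of mean signal), all probe sets with or without a symbol, moderation with an intensity trend and robust settings, array weights, a further quantile normalization within each experiment, a fit of the compared groups alone, replicate number as a block, a change of at least 1.5-fold, and each array left out in turn. Chosen after seeing the data were the interquartile range of each array as a covariate, the mean clock score of each array as a covariate, a joint quantile normalization of all 46 arrays, a fit without the 2 pregnant micro ZnO arrays that lay apart, and interaction tests of the particle arms against formulation. For every count of called probe sets the arrays were also regrouped at random into groups of the same sizes, with 100 splits that include the real one.

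The procedure was tested on simulated data with 100 of 23410 probe sets changed 1.5-fold and 100 others changed 2-fold in the same data. False calls are those outside both sets. For virgin formulation against untreated 93 were found at 1.5-fold and 99 at 2-fold, with 13 false calls. For pregnant micro ZnO against untreated 73 and 98 were found, with 11 false calls, and for the formulation interaction 51 and 94, with 10 false calls. A list shifted by 0.3 was called by camera, by camera with an estimated correlation and by fry, and 0 of 33 lists without shared members were. Each simulated probe set varied independently of the others. The test therefore cannot show how many lists or probe sets are called falsely when real genes move together. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.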

Results

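Liver RNA from 46 SKH:QS mice, a hairless laboratory stock, was hybridised to Affymetrix whole-transcript arrays, 1 array per mouse. The mice belonged to 2 separate experiments, one on virgin mice and one on pregnant mice killed on about day 17 of gestation. Sunscreen was put on the back 6 times over 4 days and the liver was taken on day 5. In each experiment 1 arm received sunscreen with micrometre-sized zinc oxide particles made from the stable isotope 68Zn (micro ZnO), 1 arm received the same with nanoparticles (nano ZnO), 1 arm received the particle-free sunscreen base (formulation) and 1 arm was left untreated. Each virgin arm held 6 mice, and the pregnant arms held 5 untreated, 6 formulation, 5 micro ZnO and 6 nano ZnO mice. The labels put the collars that limited licking in the protocol of all mice and do not say separately whether untreated mice wore them.

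The values are log2 intensities that the authors normalized with RMA. Array medians ran from 4.66 to 4.90 in virgin mice and from 3.98 to 4.12 in pregnant mice, which points to a separate normalization of each experiment that the notes do not state, so levels can be set side by side only within an experiment. Arrays of the same experiment correlated with each other at 0.974 to 0.995, and no 2 arrays held identical values. The interquartile range of the log2 values of an array was 2.97 ± 0.07 (SD, n = 6) in untreated virgin mice and 2.83 ± 0.05 (SD, n = 6) in virgin formulation mice, a difference with an exact permutation p of 0.00216 (adjusted p = 0.0260 over 12 comparisons). It was 2.91 ± 0.03 in the virgin micro ZnO arm and 2.90 ± 0.06 in the virgin nano ZnO arm. On the first principal component, which held 24.0% of the variance in virgin mice and 21.8% in pregnant mice, pregnant micro ZnO replicates 3 and 4 lay apart from the other pregnant arrays at -47.1 and -31.2. The number of arrays limits the precision of every value given here.

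**Figure D1:**
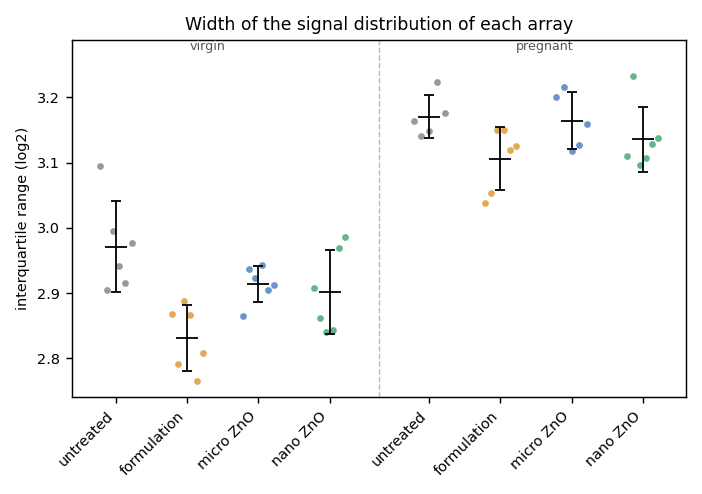
Interquartile range of the log2 values of each array (vertical axis, log2 units) for the 8 groups, with 1 point per mouse and bars for the mean and SD. The virgin formulation arrays have a mean of 2.83 ± 0.05 and the untreated virgin arrays one of 2.97 ± 0.07.

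Untreated mice were set against each sunscreen arm to find which liver transcripts changed after topical sunscreen. In virgin mice given the particle-free formulation, acute-phase and immediate early transcripts rose and male-biased liver transcripts fell. Saa2 and Saa1, which encode the secreted serum amyloid A proteins, rose by 3.98 ± 0.55 and 3.84 ± 0.52 on the log2 scale (± SE, 6 against 6 mice). Orm2, which encodes a plasma alpha-1-acid glycoprotein, rose by 3.08 ± 0.30, from 8.05 ± 0.63 to 11.14 ± 0.81 (mean ± SD of the RMA values). The transcription factor genes Jun and Atf3 rose by 2.79 ± 0.29 and 2.36 ± 0.24, and Btg2, an antiproliferative early-response gene, rose by 2.58 ± 0.25. Slco1a1, an organic anion transporter of the hepatocyte membrane, fell by 4.02 ± 0.34, and Mup3, a major urinary protein, fell by 2.00 ± 0.28. For each of these genes all 6 formulation arrays lay beyond every untreated array, and adjusted p was at most 5.20e-05.

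Of 33 measured acute-phase genes, 20 rose, 0 fell and 13 were not called, against 23 that rose when adjusted over the list alone. The camera test put the list above the other genes (median 0.45, adjusted p = 1.77e-11, adjusted p = 0.179 with an estimated correlation). Among 25 immediate early genes, 20 rose and none fell (21 adjusted over the list alone, median 0.43, camera adjusted p = 3.75e-13, adjusted p = 0.0629 with an estimated correlation). Fos, a component of the AP-1 transcription factor, rose by 2.14 ± 0.31. Of 20 male-biased liver genes, 14 fell and 6 were not called (16 fell when adjusted over the list alone, median -0.69, camera adjusted p = 4.19e-11, adjusted p = 0.0629 with an estimated correlation). Besides Slco1a1 and Mup3 these included Ugt2b1, a glucuronosyltransferase, at -0.89 ± 0.11 and Selenbp2 at -0.67 ± 0.10. The mean of the male-biased list per array, relative to the mean of the experiment, was uneven among untreated virgin mice. It was 1.09 and 0.98 in untreated replicates 3 and 5 and 0.26 to 0.45 in the others, all above every virgin sunscreen array. Hsd3b2, an enzyme of steroid metabolism, and Keg1 also fell, by 1.91 ± 0.19 and 1.55 ± 0.13.

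Genes of fatty acid oxidation under the nuclear receptor PPARA fell in the virgin formulation arm, with 20 of 37 lower and none higher (21 adjusted over the list alone). The list's median was -0.24 (camera adjusted p = 8.01e-07, adjusted p = 0.183 with an estimated correlation). Its members Hadhb, a subunit of the mitochondrial trifunctional protein, and Decr1 fell by 0.53 ± 0.08 and 0.53 ± 0.08. Among 30 antioxidant genes 9 fell and none rose, and likewise 9 and none adjusted over the list alone (median -0.16, camera adjusted p = 0.000386, adjusted p = 0.259 with an estimated correlation). Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, fell by 0.87 ± 0.12. Of 21 glucocorticoid-responsive genes 12 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 2.51e-05, adjusted p = 0.179 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, rose by 1.94 ± 0.30.

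Markers of other cell types moved in the same arm. Of 18 neutrophil markers 10 rose and none fell (11 adjusted over the list alone, median 0.40, camera adjusted p = 0.000113, adjusted p = 0.334 with an estimated correlation). Lcn2, which hepatocytes also make, rose by 2.01 ± 0.37. Of 21 endothelial markers 9 fell and none rose (10 lower and 1 higher adjusted over the list alone, median -0.27, camera adjusted p = 0.000688, adjusted p = 0.259 with an estimated correlation). Tek, a receptor of endothelial cells, fell by 0.49 ± 0.09. In all 6203 probe sets were called, 2690 higher and 3513 lower (2312 and 2925 genes), 352 of them changed at least 1.5-fold. Quantile-normalized again, the arrays gave 3971. The arm also had the narrowest arrays, and with their interquartile range as a covariate 179 were called. The SE of Orm2 grew there from 0.30 to 0.42, so lost calls alone do not show an effect of width. The covariate left Orm2, Saa1, Saa2, Jun, Atf3, Btg2, Slco1a1 and Mup3 called and ended the calls of Fos (1.35), Hadhb (-0.37), Decr1 (-0.46), Dusp1 (1.64) and Tek (-0.32).

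**Figure D2:**
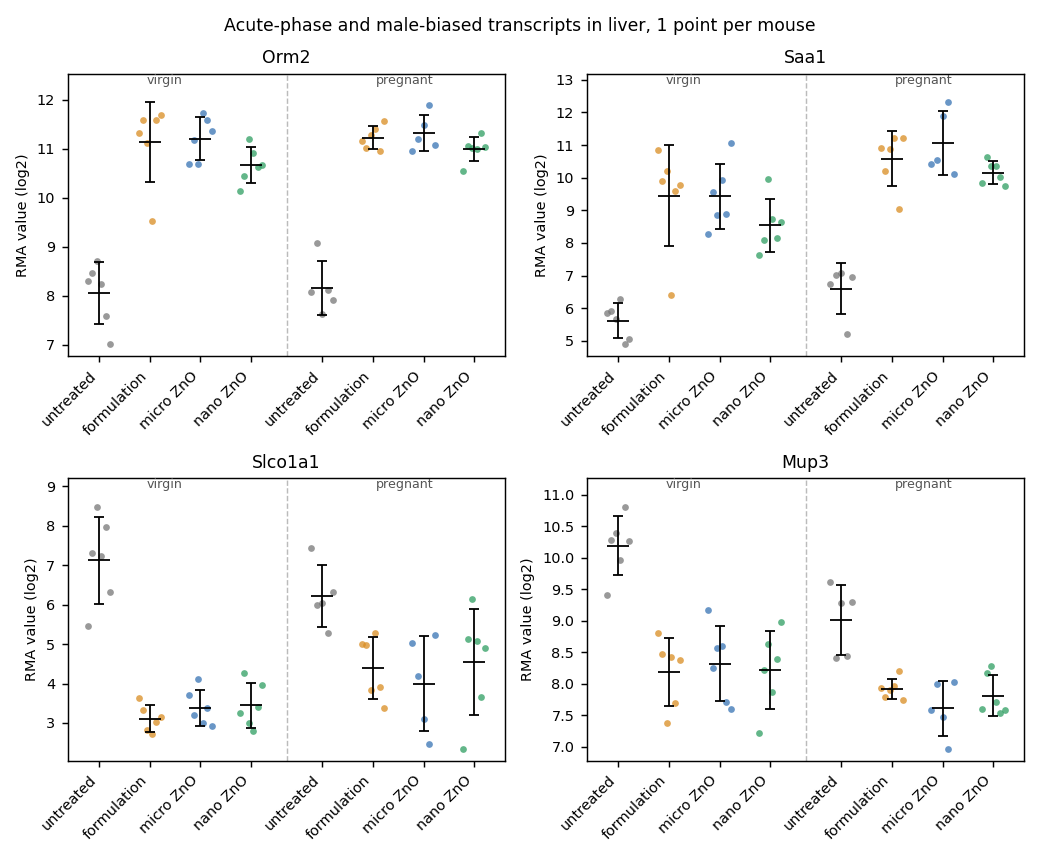
RMA values (vertical axes, log2) of acute-phase transcripts and of Slco1a1 and Mup3 in the 8 groups, with 1 point per mouse and bars for the mean and SD. Orm2 lies at 8.05 ± 0.63 in untreated virgin mice and at 11.14 ± 0.81 in virgin formulation mice, and at 8.17 ± 0.55 and 11.22 ± 0.23 in the corresponding pregnant groups.

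Virgin mice given the micro ZnO sunscreen also showed raised acute-phase transcripts, together with a shift of the clock genes. Saa1 rose by 3.82 ± 0.52, Saa2 by 3.73 ± 0.55 and Orm2 by 3.15 ± 0.30 (6 against 6 mice). Ciart, a repressor of the circadian clock, rose by 2.59 ± 0.31, and the clock-controlled transcription factor genes Dbp and Tef rose by 1.78 ± 0.32 and 1.18 ± 0.14, while Arntl, which encodes the clock activator BMAL1, fell by 1.49 ± 0.26. Cyp4a14, a fatty acid hydroxylase, rose by 2.34 ± 0.41. Slco1a1 fell by 3.74 ± 0.34, Mup3 by 1.87 ± 0.28 and Hsd3b5 by 1.41 ± 0.23. All 6 micro ZnO arrays lay beyond every untreated array for each of these genes, and adjusted p was at most 0.00171.

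In this arm 19 of 33 acute-phase genes rose and none fell (20 adjusted over the list alone, median 0.45, camera adjusted p = 1.30e-19, adjusted p = 0.0512 with an estimated correlation). Of 20 clock genes 10 rose, 2 fell and 8 were not called (15 and 3 adjusted over the list alone, median 0.56, camera adjusted p = 5.45e-08, adjusted p = 0.0332 with an estimated correlation). Per3 and Hlf were among those that rose, by 1.14 ± 0.17 and 0.46 ± 0.07. Of 20 male-biased genes 13 fell and none rose (14 adjusted over the list alone, median -0.61, camera adjusted p = 2.38e-15, adjusted p = 0.0288 with an estimated correlation). Cholesterol synthesis genes rose for 6 of 21 members and fell for none (10 adjusted over the list alone, camera adjusted p = 2.64e-05, adjusted p = 0.391 with an estimated correlation), with Msmo1 at 0.83 ± 0.13 and the squalene epoxidase gene Sqle at 0.81 ± 0.16. Endothelial markers fell for 8 of 21 members (12 adjusted over the list alone, median -0.29, camera adjusted p = 4.78e-09, adjusted p = 0.0512 with an estimated correlation), among them Cdh5, a cadherin of endothelial junctions, at -0.56 ± 0.10. Fkbp5, a glucocorticoid-induced immunophilin, rose by 1.15 ± 0.22, as did 6 of the 21 genes of its list in all (11 adjusted over the list alone, camera adjusted p = 1.21e-07, adjusted p = 0.0591 with an estimated correlation). Gclc fell by 0.82 ± 0.12.

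The micro ZnO arm differed from untreated virgin mice at 1036 probe sets, 381 higher and 655 lower (336 and 557 genes), of which 162 changed at least 1.5-fold. Leaving out 1 array lowered the count in several fits, which fewer arrays do in part by construction. It was 531 without micro ZnO replicate 1 and 650 without micro ZnO replicate 4. Without untreated replicates 1, 3, 4 and 5 it was 601, 663, 652 and 602. It was 529 with the interquartile range as a covariate and 2 with the mean clock score of each array as a covariate. Those 2 were Orm2, at 3.50 ± 0.52, and Slc39a4, at -1.08, and every other gene named for this arm lost its call in that fit. Precision fell there, with the SE of Orm2 going from 0.30 to 0.52, and Saa1 (4.81), Saa2 (4.85), Slco1a1 (-3.29) and Mup3 (-1.88) lost their calls at changes about as large as before or larger. Hsd3b5 (-1.08), Cyp4a14 (1.04) and the clock genes Ciart (0.58), Tef (0.32), Dbp (0.13) and Arntl (-0.19), on which the score itself rests in part, had smaller changes.

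Virgin mice given the nano ZnO sunscreen showed raised acute-phase and clock transcripts and lowered male-biased transcripts as well. Saa1 rose by 2.93 ± 0.52, Saa2 by 2.75 ± 0.55 and Orm2 by 2.61 ± 0.30 (6 against 6 mice). Ciart, Dbp and Tef rose by 2.25 ± 0.31, 1.91 ± 0.32 and 1.19 ± 0.14, and Arntl and Nfil3, a repressor of the same output genes, fell by 1.67 ± 0.26 and 1.45 ± 0.22. Cyp39a1, a hydroxylase of oxysterols, rose by 1.70 ± 0.18, whereas Mme, the membrane peptidase neprilysin, fell by 1.72 ± 0.19. Slco1a1 fell by 3.68 ± 0.34, Mup3 by 1.97 ± 0.28 and the fatty acid elongase gene Elovl3 by 1.34 ± 0.20. All 6 nano ZnO arrays lay beyond every untreated array for these genes, with adjusted p of at most 0.00253. The same held for A1bg, at -2.79. Among the 10 largest rises, Sult1e1 (2.00), Mfsd2a (1.88) and Alas1 (1.86) had 4, 5 and 3 of 6 arrays above every untreated array.

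Of the 33 acute-phase genes 12 rose in the nano ZnO arm (14 adjusted over the list alone, median 0.27, camera adjusted p = 3.59e-07, adjusted p = 0.311 with an estimated correlation). Clock genes rose for 12 and fell for 4 of 20 members (15 and 4 adjusted over the list alone, median 0.60, camera adjusted p = 1.44e-05, adjusted p = 0.128 with an estimated correlation). Male-biased genes fell for 14 of 20 members (15 lower and 1 higher adjusted over the list alone, camera adjusted p = 9.35e-11, adjusted p = 0.120 with an estimated correlation). Cholesterol synthesis genes rose for 11 of 21 members (12 adjusted over the list alone, camera adjusted p = 4.07e-06, adjusted p = 0.333 with an estimated correlation), including Msmo1 at 1.02 ± 0.13 and Idi1 at 0.90 ± 0.15. Antioxidant genes fell for 9 of 30 members (12 adjusted over the list alone, camera adjusted p = 3.23e-07, adjusted p = 0.156 with an estimated correlation), with Gclc at -0.93 ± 0.12 and Gstm6 at -0.89 ± 0.13. Genes of the unfolded protein response went both ways, 3 up and 9 down of 27 (4 and 15 adjusted over the list alone, camera adjusted p = 0.000919, adjusted p = 0.409 with an estimated correlation), with the disulfide isomerase gene Pdia6 at -0.63 ± 0.12. Of 18 neutrophil markers 5 rose (6 adjusted over the list alone, camera adjusted p = 1.60e-05, adjusted p = 0.311 with an estimated correlation), with S100a8 at 1.13 ± 0.30 and Ly6g at 0.63 ± 0.14. Endothelial markers fell for 9 of 21 (13 adjusted over the list alone, camera adjusted p = 1.44e-07, adjusted p = 0.128 with an estimated correlation), with Tek at -0.55 ± 0.09 and Emcn at -0.43 ± 0.09.

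In all 2796 probe sets were called between the nano ZnO arm and untreated virgin mice, 1116 higher and 1680 lower (994 and 1314 genes), of which 244 changed at least 1.5-fold. The count was 1610 without nano ZnO replicate 4 and 1723 without untreated replicate 1. It was 966 with the interquartile range as a covariate and 3 with the clock score as a covariate, and those 3 were Orm2, at 2.93 ± 0.49, Slco1a1, at -3.27, and Slc39a4, at -1.15. Every other gene named for this arm lost its call in the fit with the clock score, in which the SE of Orm2 went from 0.30 to 0.49. Saa1 (3.84), Saa2 (3.77), Mup3 (-1.98), Mme (-1.61), Cyp39a1 (1.46) and Elovl3 (-1.28) did so at changes about as large as before or larger, while Ciart (0.41), Dbp (0.39), Tef (0.39), Arntl (-0.48) and Nfil3 (-0.69) had smaller changes.

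**Figure D3:**
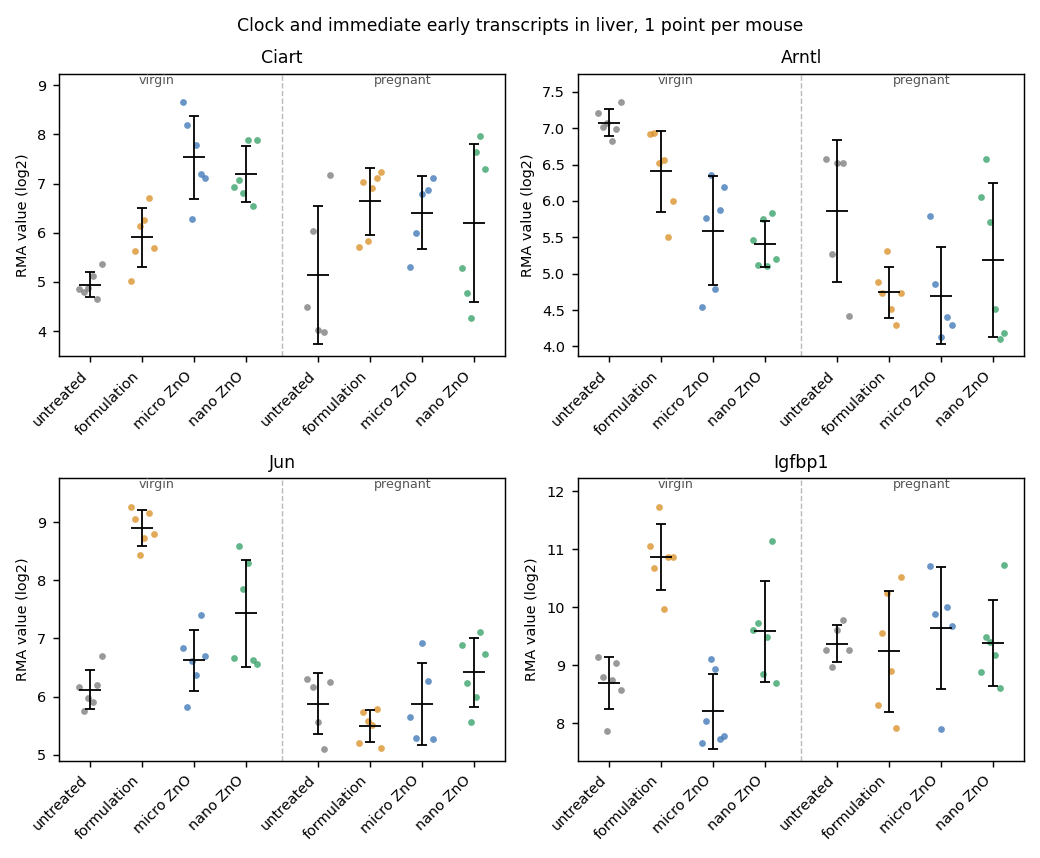
RMA values (vertical axes, log2) of the clock genes Ciart and Arntl and of the early-response genes Jun and Igfbp1 in the 8 groups, with 1 point per mouse and bars for the mean and SD. Ciart lies at 4.94 ± 0.26, 5.91 ± 0.59, 7.54 ± 0.85 and 7.19 ± 0.57 in untreated, formulation, micro ZnO and nano ZnO virgin mice, and Jun lies at 6.12 ± 0.33, 8.91 ± 0.31, 6.62 ± 0.52 and 7.43 ± 0.92 in the same groups.

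Metallothionein transcripts rose and the importer transcript Slc39a4 fell in all 3 sunscreen arms of virgin mice. The metallothionein genes Mt1 and Mt2, whose proteins bind zinc and copper, rose by 1.71 ± 0.19 and 1.97 ± 0.28 with formulation, by 1.53 ± 0.19 and 1.80 ± 0.28 with micro ZnO and by 1.38 ± 0.19 and 1.44 ± 0.28 with nano ZnO. Slc39a4, a zinc importer of the plasma membrane, fell by 1.03 ± 0.10, 1.30 ± 0.10 and 1.35 ± 0.10 in the same order, from 8.01 ± 0.17 (SD, n = 6) in untreated mice. Slc30a1, the zinc exporter of the plasma membrane, was at 0.12 ± 0.11 with formulation (adjusted p = 0.432, higher in 4 of 6 arrays than the untreated mean) and rose by 0.47 ± 0.11 with micro ZnO and by 0.40 ± 0.11 with nano ZnO. Slc30a10, a manganese exporter, fell by 1.08 ± 0.18 with nano ZnO, and its call with micro ZnO, at -0.66 ± 0.18, ended over all probe sets, with an intensity trend, after a further quantile normalization (-0.60), in a fit of these 12 arrays alone and with replicate number as a block. With the clock score as a covariate its direction reversed (0.17). The call also ended with the interquartile range (-0.56) and without micro ZnO replicate 1 (-0.51) or 4 (-0.59) or untreated replicate 1 (-0.59), 3 (-0.67), 5 (-0.67) or 6 (-0.58). Slc39a14, an importer induced in the acute phase, rose by 0.54 ± 0.15 with formulation, a call that ended with the interquartile range as a covariate (0.80). It also rose by 0.52 ± 0.15 with micro ZnO and by 0.45 ± 0.15 with nano ZnO (adjusted p = 0.0421 and 0.0465, with 6 of 6 arrays above every untreated array in both). Those 2 calls ended in 9 and 10 fits that left out 1 array (0.48 to 0.56 and 0.36 to 0.46), over all probe sets, with an intensity trend, with replicate number as a block and with the clock score as a covariate (0.57 and 0.49), and that with nano ZnO also with array weights (0.42). For Mt1 and Slc39a4 all 6 arrays of each arm lay beyond every untreated array, and adjusted p was at most 0.000139.

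Between the virgin particle arms and the virgin formulation arm neither metallothionein gene was called, with Mt1 at -0.18 ± 0.19 for micro ZnO and -0.33 ± 0.19 for nano ZnO (adjusted p = 0.630 and 0.403) and Mt2 at -0.17 ± 0.28 and -0.53 ± 0.28. Slc39a4 was also not called there, at -0.26 ± 0.10 and -0.32 ± 0.10 (adjusted p = 0.117 and 0.0830), but it was called after a further quantile normalization (-0.33 and -0.38, adjusted p = 0.0380 and 0.0246) and, for nano ZnO, with the interquartile range as a covariate (-0.43, adjusted p = 0.0457). Slc30a1 was higher with micro ZnO than with formulation by 0.36 ± 0.11 (adjusted p = 0.0394, above the formulation mean in 6 of 6 arrays), a call that ended in 9 fits that left out 1 array (formulation replicates 1, 2, 4 and 6 and micro ZnO replicates 1, 2, 4, 5 and 6, at 0.28 to 0.38) and after a further quantile normalization (0.26). It was at 0.28 ± 0.11 with nano ZnO (adjusted p = 0.145). Slc30a10 was lower with nano ZnO than with formulation, at -0.65 ± 0.18 (adjusted p = 0.0427, below the formulation mean in 6 of 6 arrays), and this call ended in 9 such fits (formulation replicates 1, 2, 4 and 6 and nano ZnO replicates 1, 2, 4, 5 and 6, at -0.70 to -0.55). Between nano ZnO and micro ZnO none of the 6 zinc genes was called, with Slc30a10 at -0.42 ± 0.18. The calls of Slc30a1 with micro ZnO and of Slc30a10 with nano ZnO against formulation also ended with either covariate, over all probe sets, in a fit of the compared groups alone and with replicate number as a block, and that of Slc30a10 with an intensity trend as well. Among 11 metallothionein and MTF1 target genes 4 rose and 2 fell with formulation (6 and 3 adjusted over the list alone, camera adjusted p = 0.109). Of 14 zinc importers 2 rose and 5 fell there, counts that were also found adjusted over the list alone (camera adjusted p = 0.0664). With the clock score as a covariate the calls of Mt1 against untreated mice ended in the micro ZnO and nano ZnO arms (1.27 and 1.14), as did those of Mt2 (1.46 and 1.13), of Slc30a1 (0.0026 and -0.034) and, for nano ZnO, of Slc30a10 (-0.32). The call of Slc30a1 with nano ZnO also ended with the interquartile range as a covariate (0.41).

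**Figure D4:**
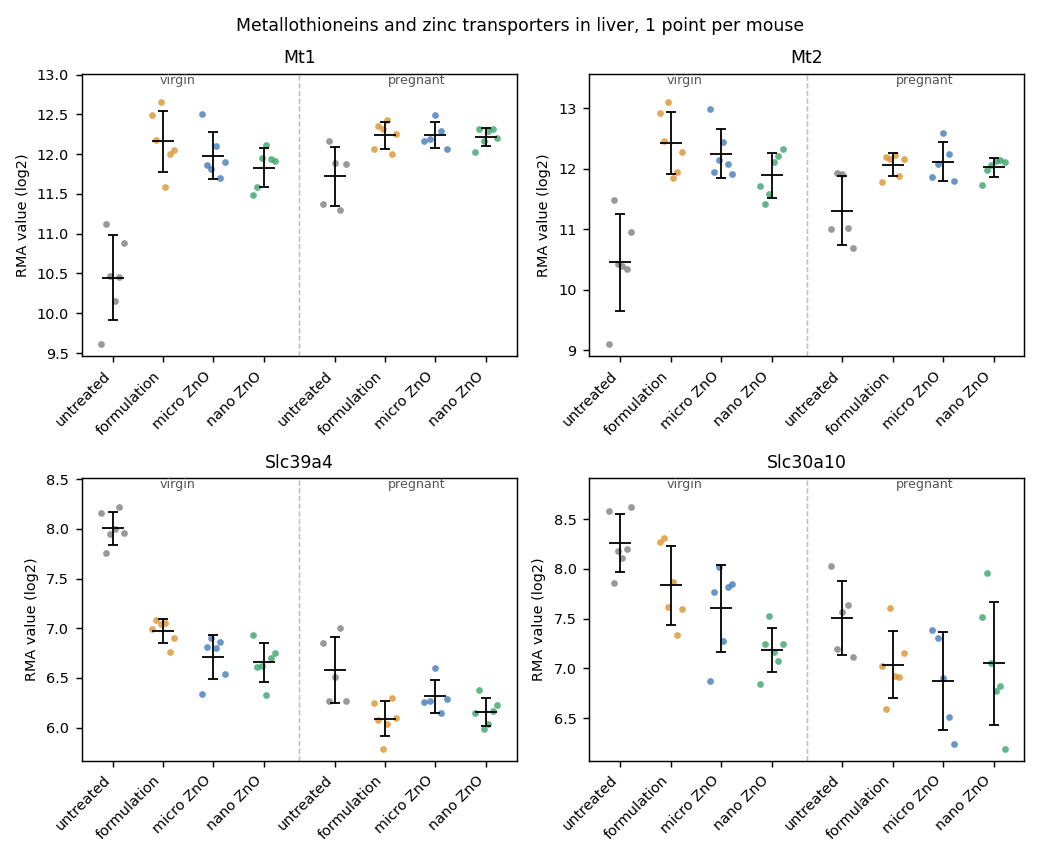
RMA values (vertical axes, log2) of Mt1, Mt2, Slc39a4 and Slc30a10 in the 8 groups, with 1 point per mouse and bars for the mean and SD. Mt1 lies at 10.45 ± 0.53 in untreated virgin mice and at 12.16 ± 0.38, 11.98 ± 0.29 and 11.83 ± 0.24 in the virgin formulation, micro ZnO and nano ZnO arms, while Slc39a4 lies at 8.01 ± 0.17 in untreated virgin mice and below in all 3 arms.

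The micro ZnO and formulation arms of virgin mice were compared to separate the particles from the base that carried them. Immediate early transcripts were lower with micro ZnO than with formulation alone, and genes of fatty acid oxidation were higher. Igfbp1, an insulin-like growth factor binding protein induced by stress and fasting, differed by -2.66 ± 0.33, and Jun, Btg2 and Atf3 differed by -2.28 ± 0.29, -2.02 ± 0.25 and -1.95 ± 0.24, with all 6 micro ZnO arrays below every formulation array and adjusted p of at most 7.91e-05. Cyp4a14, Ciart and the cell cycle kinase gene Wee1 were higher by 1.88 ± 0.41, 1.63 ± 0.31 and 1.14 ± 0.22, each in 6 of 6 arrays relative to the formulation mean, with adjusted p of at most 0.00687. Of 25 immediate early genes 12 were lower and none higher (13 adjusted over the list alone, median -0.44, camera adjusted p = 5.69e-17, adjusted p = 0.0305 with an estimated correlation). Of 37 PPARA targets 14 were higher and 1 lower (19 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 5.90e-13, adjusted p = 0.0636 with an estimated correlation), among them Hadhb at 0.55 ± 0.08 and the mitochondrial carnitine carrier gene Slc25a20 at 0.56 ± 0.09. Female-biased genes were higher for 5 of 18 members (also 5 adjusted over the list alone, camera adjusted p = 3.26e-05, adjusted p = 0.0636 with an estimated correlation), among them the flavin monooxygenase gene Fmo2 at 0.97 ± 0.20.

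The contrast held 1599 called probe sets, 1203 higher and 396 lower with micro ZnO (1016 and 277 genes), of which 144 differed at least 1.5-fold. The arrays of the micro ZnO arm were wider than those of the formulation arm, with an exact permutation p of 0.00866 for their interquartile range (adjusted p = 0.0519). The count was 214 with the interquartile range as a covariate, 225 with the clock score as a covariate, 1046 and 847 without formulation replicates 2 and 5, and 991 without micro ZnO replicate 2. With the clock score Ciart (0.60), Cyp4a14 (1.21), Wee1 (0.69) and Fmo2 (0.67) lost their calls, and Fmo2 also lost it with the interquartile range (0.92).

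Immediate early transcripts were also lower with nano ZnO than with formulation in virgin mice. Jun, Fos, Btg2 and Atf3 differed by -1.47 ± 0.29, -1.65 ± 0.31, -1.22 ± 0.25 and -1.15 ± 0.24, with 6, 6, 6 and 5 of 6 arrays below the formulation mean and adjusted p of at most 0.00989. Idi1, an isomerase of cholesterol synthesis, was higher by 0.99 ± 0.15, Nampt, which makes a precursor of NAD, by 1.00 ± 0.20, and Keg1 by 1.03 ± 0.13. Immediate early genes were lower for 6 of 25 members (9 adjusted over the list alone, median -0.27, camera adjusted p = 5.20e-10, adjusted p = 0.179 with an estimated correlation). Cholesterol synthesis genes were higher for 7 of 21 members (10 adjusted over the list alone, camera adjusted p = 1.75e-09, adjusted p = 0.278 with an estimated correlation), with Msmo1 at 0.81 ± 0.13. Genes of bile acid synthesis and transport were higher for 5 of 30 (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.14e-05, adjusted p = 0.179 with an estimated correlation), with the bile acid receptor gene Nr1h4 at 0.45 ± 0.09. In all 760 probe sets were called, 591 higher and 169 lower (502 and 110 genes), 68 of them at least 1.5-fold apart. When the arrays were quantile-normalized again 494 were higher and 266 lower. The count was 156 with the interquartile range as a covariate, 32 with the clock score as a covariate and 189 in a fit of these 12 arrays alone. It was 495, 396, 427 and 486 without formulation replicates 1, 2, 5 and 6, and 374, 499 and 251 without nano ZnO replicates 1, 5 and 6. Both covariates ended the calls of Jun (-1.12 with the interquartile range and -1.20 with the clock score), Fos (-1.25 and -1.22), Btg2 (-0.93 and -0.95), Atf3 (-0.88 and -1.13), Nampt (0.75 and 0.70) and Nr1h4 (0.38 and 0.45), and the clock score ended that of Msmo1 (0.65). The calls of Btg2 and Atf3 also ended in the fit of these arrays alone. Keg1 and Idi1 kept their calls in all of these fits.

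Particle size was addressed by setting nano ZnO against micro ZnO. In virgin mice no probe set was called by limma, with 1106 at unadjusted p under 0.05 against 1170.5 by chance and a smallest adjusted p of 0.961. The smallest p values belonged to Cyp2d40, a cytochrome P450 gene, at -0.55 ± 0.12, Psrc1 at 0.34 ± 0.08 and the olfactory receptor gene Olfr920 at 0.32 ± 0.07. Camera called 13 of 41 lists, 5 of them higher with nano ZnO, and none was called with an estimated correlation or by fry. In pregnant mice the same contrast also called 0 probe sets by limma, with 1086 at unadjusted p under 0.05 and a smallest adjusted p of 0.979. Saa3, a serum amyloid gene, was at -2.60 ± 0.59 there, with 6 of 6 nano ZnO arrays below the micro ZnO mean. That mean includes pregnant micro ZnO replicates 3 and 4, which lay apart. Without them the difference of Saa3 between the experiments for micro ZnO went from 3.92 to 2.45, so the value rests in part on these mice. Camera called 10 lists in pregnant mice, 1 of them higher, against 0 with an estimated correlation and 0 by fry.

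Pregnant mice carried the acute-phase rise in all 3 sunscreen arms and little else that passed. Yet 2890, 2126 and 2396 probe sets had an unadjusted p under 0.05 with formulation, micro ZnO and nano ZnO, against 1170.5 by chance. Slco1a1 was not called. Its means there were 4.39 ± 0.79, 4.00 ± 1.20 and 4.55 ± 1.34 (SD), against 6.22 ± 0.79 in untreated mice. Sult1e1 was called at 3.02 with formulation and 3.09 with micro ZnO, calls that ended in 9 and 4 fits that left out 1 array. With formulation Saa3 rose by 4.20 ± 0.59, Saa1 by 3.99 ± 0.40, Saa2 by 3.68 ± 0.40, Orm2 by 3.06 ± 0.20 and Orm1 by 0.82 ± 0.10 (6 against 5 mice), with all 6 formulation arrays above every untreated array and adjusted p of at most 0.00117. Of 33 acute-phase genes 8 rose and none fell, against 17 adjusted over the list alone (median 0.41, camera adjusted p = 6.55e-25, adjusted p = 0.121 with an estimated correlation). Hp, the hemoglobin-binding haptoglobin gene, was called at 0.66 ± 0.11 but not without untreated replicate 1, at 0.62 (adjusted p = 0.0606). Its call and that of Saa3 also ended with the interquartile range as a covariate (0.61 and 3.51). The other 7 called genes each lost the call in several fits that left out 1 array. The 14 called probe sets, 9 higher and 5 lower, became 10 higher and 3 lower after a further quantile normalization. Their number was 8, 6, 6, 9 and 7 without formulation replicates 1, 2, 3, 4 and 6 and 5, 6, 7 and 8 without untreated replicates 1, 3, 4 and 5. It was 4 with the interquartile range as a covariate, 6 with the clock score as a covariate, 6 over all 35512 probe sets, 39 with array weights and 53 in a fit of these 11 arrays alone.

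With micro ZnO, pregnant mice showed raised acute-phase and neutrophil transcripts. Saa3 rose by 5.36 ± 0.62, Saa1 by 4.46 ± 0.42, Saa2 by 3.99 ± 0.42, Orm2 by 3.16 ± 0.20, Orm3 by 1.64 ± 0.28 and Orm1 by 0.92 ± 0.10, Retnlg, a resistin-like gene of neutrophils, rose by 1.32 ± 0.21, and Mup3 fell by 1.40 ± 0.22 (5 against 5 mice). All 5 micro ZnO arrays lay beyond every untreated array for each, with adjusted p of at most 0.00932. Acute-phase genes rose for 10 of 33 members (23 adjusted over the list alone, median 0.63, camera adjusted p = 2.86e-39, adjusted p = 0.0170 with an estimated correlation). Neutrophil markers rose for 4 of 18 (16 adjusted over the list alone, median 0.80, camera adjusted p = 5.42e-25, adjusted p = 0.0654 with an estimated correlation). No NF-kB or inflammatory mediator gene passed limma over all genes, while 20 of 25 were higher when adjusted over the list alone (camera adjusted p = 1.17e-17, adjusted p = 0.211 with an estimated correlation). The mean of that list in each array, relative to the mean of the experiment, was raised in 2 arrays, at 1.63 and 1.24 in micro ZnO replicates 3 and 4, -0.26, -0.16 and -0.16 in replicates 1, 2 and 5 and -0.29 to -0.19 in untreated mice. The neutrophil markers were at 1.25 and 1.10 in the same 2 arrays, -0.018 to 0.22 in the other 3 and -0.75 to -0.42 in untreated mice, and the acute-phase genes at 1.11 and 0.99, -0.059 to 0.14 and -0.93 to -0.49. S100a8, a calprotectin subunit of neutrophils, was at 2.23 ± 0.41 and lost its call without micro ZnO replicate 3 (1.97) or 4 (2.03) or untreated replicate 1 (2.02), 3 (2.25) or 5 (2.24), over all probe sets and with an intensity trend (adjusted p = 0.0811 for both). Without replicates 3 and 4 together, which lay apart on the first principal component, its call ended (1.62), as did those of Retnlg (0.99), Orm3 (1.31) and Mup3 (-1.14), and in a fit of these 10 arrays alone those of S100a8, Orm3 and Mup3 ended at unchanged values. Of 25 called probe sets 17 were higher and 8 lower. Their number was 138, 12 and 13 without micro ZnO replicates 2, 3 and 4, and 12, 46, 11 and 15 without untreated replicates 1, 2, 3 and 5. It was 7 without micro ZnO replicates 3 and 4 together, 38 with the interquartile range as a covariate, 13 over all probe sets and 8 in a fit of these 10 arrays alone. Without micro ZnO replicate 3 the camera calls fell from 18 lists to 10.

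With nano ZnO, pregnant mice had 5 called probe sets. Saa1 rose by 3.56 ± 0.40, Saa2 by 3.20 ± 0.40, Orm2 by 2.82 ± 0.20 and Orm1 by 0.71 ± 0.10 (6 against 5 mice, adjusted p of at most 0.00114), with all 6 nano ZnO arrays above every untreated array. Mup3 was at -1.20 ± 0.21 and lost its call without nano ZnO replicates 1 (-1.16), 4 (-1.18), 5 (-1.14) or 6 (-1.15) or untreated replicates 1 (-1.05), 3 (-1.13) or 5 (-1.12), with either covariate (-1.14 and -1.11), over all probe sets, with an intensity trend, in a fit of these 11 arrays alone and with replicate number as a block (adjusted p = 0.0963, 0.0547, 0.0694 and 0.0721). Acute-phase genes rose for 4 of 33 members (13 adjusted over the list alone, median 0.39, camera adjusted p = 3.87e-20, adjusted p = 0.175 with an estimated correlation). The count was 10 without nano ZnO replicate 2 and 10 without untreated replicate 2, 13 with array weights and 11 in a fit of these 11 arrays alone.

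None of the 6 zinc genes was called in a sunscreen arm of pregnant mice in the model with the 4 arms, while Mt2 was called with micro ZnO when replicate number was a block (0.80, adjusted p = 0.0454). Mt1 was at 0.51 ± 0.13, 0.52 ± 0.13 and 0.50 ± 0.13 and Mt2 at 0.76 ± 0.18, 0.80 ± 0.19 and 0.71 ± 0.18 with formulation, micro ZnO and nano ZnO, with adjusted p of at least 0.0965. Every array of the 3 arms lay above the untreated mean for both genes. Slc39a4 was at -0.49 ± 0.12, -0.27 ± 0.13 and -0.42 ± 0.12, with adjusted p of 0.175, 0.543 and 0.277. Without untreated replicate 2, Mt1 and Mt2 were called with formulation (0.62 and 0.91, adjusted p = 0.0362 for both) and with micro ZnO (0.63 and 0.96). Pregnant untreated mice already held Mt1 at 11.72 ± 0.37 (SD, n = 5), in an experiment whose levels are shifted against those of virgin mice.

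Between the particle arms and the formulation arm of pregnant mice no probe set was called by limma. For micro ZnO 1639 probe sets had an unadjusted p under 0.05, and the smallest adjusted p was 0.168, shared by Timd4, a phosphatidylserine receptor of resident macrophages, at 0.73 ± 0.13, Hivep2 at 0.70 ± 0.13 and Nrp2 at 0.41 ± 0.08. Of 20 macrophage markers none was called over all genes, 14 were higher when adjusted over the list alone, and camera placed the list above other genes (adjusted p = 2.55e-17, adjusted p = 0.0847 with an estimated correlation). Without micro ZnO replicate 2 the count was 41 and Timd4, Hivep2 and Nrp2 were called. For nano ZnO 718 probe sets had an unadjusted p under 0.05, fewer than the 1170.5 of chance, and the smallest adjusted p was 0.0788 for A3galt2, a galactosyltransferase gene, at -0.45 ± 0.08, with 6 of 6 arrays below every formulation array. It was called without formulation replicate 4, at -0.49, and after a further quantile normalization the count was likewise 1. Camera called 10 lists for micro ZnO and 8 for nano ZnO, against 0 and 0 with an estimated correlation and 1 and 0 by fry. For nano ZnO the lists were 4 and 5 without formulation replicates 2 and 3.

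Whether the virgin and the pregnant response differ was asked by interaction tests over all 8 groups. Each state was studied in its own experiment, so a difference between the responses cannot be told apart from one between the experiments. For formulation 34 probe sets differed, 18 higher and 16 lower in the pregnant response. Jun rose in virgin mice (2.79 ± 0.29) and was at -0.39 ± 0.29 in pregnant mice, a difference of -3.18 ± 0.43 (adjusted p = 7.46e-05). Btg2, Atf3, Fos, Zfp36 and Nr4a1 differed in the same direction, by -2.67 ± 0.42, -2.35 ± 0.40, -2.17 ± 0.38, -1.91 ± 0.32 and -1.42 ± 0.26, and the cytochrome P450 gene Cyp2c67 differed by 1.43 ± 0.26. Immediate early genes were lower in the difference for 9 of 25 members (12 adjusted over the list alone, median -0.39, camera adjusted p = 1.50e-21, adjusted p = 0.00275 with an estimated correlation). Of 20 male-biased genes 1 was higher in the difference, against 11 adjusted over the list alone (median 0.65, camera adjusted p = 3.36e-13, adjusted p = 0.00281 with an estimated correlation). For Mt1 the difference was -1.20 ± 0.25 (adjusted p = 0.0205), and its call ended without virgin untreated replicate 4 (-1.14) or pregnant untreated replicate 2 (-1.09), in a fit of the compared groups alone (adjusted p = 0.0846) and with replicate number as a block (adjusted p = 0.0713). The count was 20 without virgin untreated replicate 4, 18 without pregnant untreated replicate 1 and 11 with replicate number as a block.

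For micro ZnO 11 probe sets differed, 9 higher and 2 lower. Slc39a4 fell in virgin mice (-1.30 ± 0.10) and was at -0.27 ± 0.13 in pregnant mice, a difference of 1.03 ± 0.16 (adjusted p = 0.00308). Serpinb1a, an inhibitor of neutrophil proteases, differed by 1.42 ± 0.24, Ly6e by 1.06 ± 0.19 and the neurotrophin receptor gene Ntrk2 by 0.85 ± 0.15. Without pregnant micro ZnO replicates 3 and 4 together Ly6e (0.79), Saa3 (2.45), Rac2 (0.63), Cxcl16 (0.56), Lcp1 (0.49), Cyp4a14 (-2.36) and Nim1k (-0.58) lost their calls, and the count was 6, of which 3 were among the 11. The call of Ly6e also ended in a fit of these 4 groups alone. The count was 49, 23, 6, 5 and 46 without pregnant micro ZnO replicates 1 to 5, 5 without virgin micro ZnO replicate 1, and 6, 6 and 7 without pregnant untreated replicates 1, 2 and 4. It was 5 over all probe sets and 5 in a fit of these 4 groups alone. For nano ZnO 10 probe sets differed, 9 higher and 1 lower. Slc39a4 again differed, by 0.93 ± 0.16 (-1.35 ± 0.10 in virgin and -0.42 ± 0.12 in pregnant mice, adjusted p = 0.00405), together with A1bg at 2.51 ± 0.45, the bile acid transporter gene Slc10a2 at 2.06 ± 0.35, Serpinb1a at 1.41 ± 0.23 and Cyp2a22 at -1.93 ± 0.35. With replicate number as a block the count was 6. Camera called 5, 10 and 9 lists for the 3 interactions and 3, 0 and 0 with an estimated correlation.

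Fold changes across the 23410 probe sets correlated between the experiments at Pearson r = 0.536 for formulation, 0.398 for micro ZnO and 0.535 for nano ZnO. Genes are not independent replicates, so r was set against 100 arrangements of the arm labels, the real one included, and the highest of the other r values was 0.394, 0.283 and 0.242. Of the 14, 25 and 5 probe sets called in pregnant mice, 13, 10 and 4 were called in virgin mice with the same sign. Mup3, Orm2, Saa1 and Saa2 were among them in every arm. Of the probe sets called in virgin mice 85.8%, 80.2% and 88.3% had the same sign in pregnant mice. With the labels of the pregnant arrays permuted, 2, 9 and 1 of 100 arrangements, the real one included, gave as large a share, and the highest of the others were 86.0%, 86.1% and 87.0%. Arms of an experiment share their untreated mice, which alone makes their fold changes correlate. In virgin mice micro ZnO and nano ZnO correlated at 0.856, against a mean of 0.508 and a highest of 0.791 in simulated data without any arm effect, and at 0.607 when each arm was given its own part of the untreated mice. Formulation correlated with micro ZnO at 0.643 (simulated mean 0.454, highest 0.780) and with nano ZnO at 0.730 (simulated mean 0.513, highest 0.784), and at 0.457 and 0.551 with separate untreated mice. In pregnant mice formulation correlated with micro ZnO at 0.659 and with nano ZnO at 0.806, and micro ZnO with nano ZnO at 0.730, against simulated highest values of 0.820, 0.784 and 0.808, and the 3 pairs were at 0.369, 0.441 and 0.408 with separate untreated mice. The covariance of each pair lay above its simulated mean, from 0.0291 against 0.00551 to 0.0367 against 0.00636 in virgin mice and from 0.0226 against 0.0102 to 0.0239 against 0.00839 in pregnant mice.

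Untreated pregnant mice were set against untreated virgin mice for the baseline of each experiment (5 against 6). Array medians differed between the experiments, and on the deposited values 21390 probe sets were called by limma, 193 higher and 21197 lower, with a median difference of -0.61. After a joint quantile normalization of all arrays 7442 were called, 3269 higher and 4173 lower, with a median of -0.02. On that scale Cyp3a16, a cytochrome P450 of fetal and neonatal liver, was higher by 5.65 ± 0.49, Dnajc12, a cochaperone gene, by 3.36 ± 0.36, Lifr, the receptor of leukemia inhibitory factor, by 2.91 ± 0.25 and Mt1 by 1.77 ± 0.18. Cyp2b13, a female-biased cytochrome P450, was at -3.59 ± 0.22, Cyp4a14 at -3.57 ± 0.35, the complement gene C9 at -2.58 ± 0.20, Elovl3 at -1.72 ± 0.21 and Slc39a4 at -0.94 ± 0.11. As a list the female-biased genes leaned the other way than Cyp2b13, with 9 of 18 higher and 4 lower. Their median was 0.57 (camera adjusted p = 0.00892, adjusted p = 0.420 with an estimated correlation). Of 33 acute-phase genes 18 were higher and 1 lower, of 18 neutrophil markers 12 were higher and none lower, and of 20 male-biased genes none was higher and 11 were lower. The camera calls of these 3 lists there (adjusted p = 3.37e-06, 1.39e-06 and 0.000518) did not hold with an estimated correlation (adjusted p = 0.420 for each). On the deposited scale the acute-phase list had a median of -0.08 and a mean of 0.03, and camera placed it above other genes, while most genes lay lower there. Pregnancy, experiment and normalization cannot be told apart here.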

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

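The tests of leukocytes, of the phase of the clock and of the same contrast in pregnant mice were chosen after the results were seen, as were both covariates, the immediate early score, the fit without pregnant micro ZnO replicates 3 and 4, the joint quantile normalization and the interaction of the particle arms with formulation.

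Acute-phase transcripts were higher in all 3 sunscreen arms of both experiments, with Orm2 up by 2.61 to 3.16. Leukocytes entering the liver bring their own abundant transcripts, and in 6 of 6 comparisons Orm2 rose above the change plus 2 SE of each of 7 such transcripts, the highest being S100a8 at 2.23 ± 0.41 in pregnant micro ZnO mice, where its upper bound of 3.04 lay closest to Orm2 at 3.16. The bound was itself chosen after the values were seen, and a stricter first form of it, which asked that macrophage and T cell medians not exceed 0 and that S100a8 and S100a9 not be called, was met in 0 of 6. Orm2 stayed called in 6 of 6 comparisons with the clock score as a covariate and in 6 of 6 with the interquartile range. The latter argues against the width of the arrays as the whole cause for Orm2. The clock score cannot decide on the time of killing, since it averages clock genes of opposite phase. In virgin mice it also lay lower in every untreated array (-0.36 to -0.32) than in any sunscreen array. In pregnant mice, where the scores overlapped, Orm2 stayed at 2.74 to 3.06. As a group the acute-phase calls went from 20 to 12 and from 8 to 4 in virgin and pregnant formulation mice with the interquartile range. They went from 19 to 1 and from 12 to 1 in virgin micro ZnO and nano ZnO mice with the clock score. There the error of Orm2 grew from 0.30 to 0.52 and 0.49, while its change went from 3.15 to 3.50 and from 2.61 to 2.93. For most other acute-phase genes the change in that fit is not given here, so why their calls ended stays open. An inflammatory response of the treated animals, to the sunscreen base, to collars, licking or handling, or to another part of the protocol may explain the pattern, as a hypothesis, and the labels give no group that separates these.

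Clock genes were higher in the virgin sunscreen arms than in untreated virgin mice. A different phase of the daily rhythm at killing would put Arntl, Clock, Cry1 and Nfil3 lower and Per3, Ciart, Tef and Dbp higher, as they were in 3 of 3 virgin arms (-0.39 ± 0.19, -0.84 ± 0.18 and -1.02 ± 0.09 against 0.69 ± 0.20, 1.68 ± 0.27 and 1.63 ± 0.10 for formulation, micro ZnO and nano ZnO), with an exact permutation p of 0.0649 for the first of these values, but the 8 genes were picked after their values had been seen, so this gives a phase shift no independent support. In pregnant mice the group with Arntl was at -0.67 ± 0.24, -0.55 ± 0.26 and -0.37 ± 0.31 in the same order of arms. The group with Per3 was at 1.08 ± 0.48, 0.85 ± 0.51 and 0.57 ± 0.64 there. Exact permutation p was 0.0216 and 0.0671 for formulation and at least 0.0794 for the particle arms. The direction was thus not particular to virgin mice. The width of the arrays as the whole cause is argued against by the clock genes called, of which 68.8% with nano ZnO (11 of 16) and more with micro ZnO (10 of 12) kept their call with the interquartile range as a covariate. A later or earlier time of killing and a treatment that shifts the clock, by stress or feeding for instance, may each explain it, and the labels give no time of killing for any mouse.

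The virgin formulation arm differed from both virgin particle arms. Its arrays were narrower on average, though the exact permutation tests against micro ZnO and nano ZnO did not pass (adjusted p = 0.0519 and 0.160). The 1599 probe sets called for micro ZnO against formulation became 214 with the interquartile range as a covariate, 164 of them shared, while the median absolute change of the 1599 went from 0.36 to 0.26 at a median SE of 0.0900 and 0.0935. With the mean of the immediate early genes as a covariate 23 were called, 4 of them shared, and the median absolute change went to 0.15 at an SE of 0.158, so the calls ended both because the changes shrank and because this score moves with the arm. Of the probe sets called in virgin mice, 39 for micro ZnO and 2 for nano ZnO were also called as different between the experiments. That count cannot place the difference in the formulation, since the particle arm enters the test and the virgin contrast is part of it. It was not refitted without pregnant micro ZnO replicates 3 and 4. Against untreated mice the formulation response itself differed at 34 probe sets, which argues against the same response in pregnant mice at those. The handling of this arm's animals or RNA shortly before or after death may explain the early-response genes, and a true effect of particles on the response to the base stays open, since the arm is a single group of 6 mice.

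For most counts of called probe sets, few random splits of the arrays called as many as the real grouping. The smallest share that can be reached is 1 in 100, and the shares were not adjusted over comparisons. The splits move single mice and do not cover a structure shared by several of them. Among 100 splits that include the real one, 1 called as many probe sets as the real one for virgin formulation (6203, highest other 3420), micro ZnO (1036, 79), nano ZnO (2796, 566), micro ZnO against formulation (1599, 42) and nano ZnO against formulation (760, 481), for pregnant formulation (14, 2) and nano ZnO (5, 1), for the formulation interaction (34, 1) and for pregnant against virgin untreated mice (21390, 17415). The number was 2 of 100 for pregnant micro ZnO (25, 35), for the micro ZnO interaction (11, 129) and for the nano ZnO interaction (10, 12). It was 100 of 100 for nano ZnO against micro ZnO in virgin mice (0, 56) and in pregnant mice (0, 817) and for micro ZnO (0, 0) and nano ZnO (0, 1) against formulation in pregnant mice, where limma called no probe set in the real grouping, so that every split calls as many and the number decides nothing about chance, with 1106, 1086, 1639 and 718 at unadjusted p under 0.05. A split with 817 calls, and one with 129 where the real count was 11, points to a structure of the samples, as does the separation of pregnant micro ZnO replicates 3 and 4 from the other arrays. The correlation of fold changes between the experiments was as large in 1 of 100 permutations for each of formulation (0.536, highest other 0.394), micro ZnO (0.398, 0.283) and nano ZnO (0.535, 0.242).

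Single arrays far from the others of their group were found by Dixon's test in 7 of 128 groups of values, and chance flags about 1 in 20 groups. Virgin formulation replicate 4 was lowest for Orm2 at 9.53 (the others from 11.11 to 11.69), for Saa1 at 6.41 (9.58 to 10.86) and for Saa2 at 7.93 (10.70 to 12.31). Pregnant untreated replicate 4 was lowest for Saa1 at 5.20 (6.74 to 7.07). Virgin nano ZnO replicate 6 was highest for Slc39a14 at 9.28 (8.65 to 8.85), and pregnant nano ZnO replicate 1 was highest for S100a8 at 8.78 (5.95 to 6.84). Pregnant nano ZnO replicate 2 had the widest array of its group, with an interquartile range of 3.23 (3.10 to 3.14).

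Interaction tests found 34 probe sets whose response to formulation differed between pregnant and virgin mice. Here and for the particle arms, pregnancy and experiment cannot be told apart. The difference was 1.73 for Slc10a2, 1.48 for Keg1, 1.46 for Hsd3b2, 1.43 for Cyp2c67, 1.10 for Vamp7, 1.06 for Ces3a, 0.77 for C8b, 0.71 for Apoa4, 0.67 for Ugt2b38 and 0.66 for Ntrk2. It was -3.18 for Jun, -2.67 for Btg2, -2.59 for Dusp1, -2.52 for Egr1, -2.35 for Atf3, -2.17 for Fos, -1.91 for Zfp36, -1.53 for Ier2, -1.42 for Nr4a1 and -1.20 for Mt1. Calls ended in fits that left out 1 array for Egr1 (17 fits, -2.61 to -2.22), Dusp1 (16 fits, -2.63 to -2.29), Keg1 (14 fits, at 1.38 or more), Ntrk2 (13 fits, 0.58 to 0.67), Ces3a (11 fits, 0.97 to 1.06), C8b (9 fits, 0.65 to 0.76) and Hsd3b2 (8 fits, 1.35 to 1.46). They ended without pregnant untreated replicate 1 for Ier2 (-1.31), replicate 4 for Slc10a2 (1.44), replicate 5 for Apoa4 (0.64) and replicate 2 for Mt1 (-1.09), and for Mt1 also without virgin untreated replicate 4 (-1.14). Over all probe sets and with an intensity trend the calls of Keg1, Dusp1 and Egr1 ended, and with the trend also that of Ces3a. A further quantile normalization ended that of Keg1, array weights that of Ntrk2, and a fit of the compared groups alone those of Egr1, Slc10a2, C8b and Mt1. With replicate number as a block those of Keg1, Dusp1, Egr1, Ces3a, Ntrk2, C8b, Mt1, Hsd3b2, Vamp7, Apoa4, Ugt2b38 and Ier2 ended.

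For micro ZnO 11 probe sets differed between pregnant and virgin mice, with differences of 3.92 for Saa3, 1.42 for Serpinb1a, 1.06 for Ly6e, 1.04 for Rac2, 1.03 for Slc39a4, 0.89 for Cxcl16, 0.85 for Ntrk2, 0.69 for Lcp1, -2.37 for Cyp4a14 and -0.61 for Nim1k. Calls ended in fits that left out 1 array for Cxcl16 (15 fits, 0.77 to 0.92), Saa3 (13 fits, 3.31 to 3.98), Cyp4a14 (11 fits, -2.41 to -2.17), Rac2 (6 fits, 0.87 to 1.03) and Lcp1 (6 fits, 0.58 to 0.67). Without pregnant micro ZnO replicates 3 and 4 together those of Saa3 (2.45), Ly6e (0.79), Rac2 (0.63), Cxcl16 (0.56), Lcp1 (0.49), Cyp4a14 (-2.36) and Nim1k (-0.58) ended, so that Serpinb1a, Slc39a4 and Ntrk2 remained. Over all probe sets Saa3, Rac2, Cxcl16, Lcp1 and Cyp4a14 lost their calls, in a fit of the compared groups alone these and Ly6e, with an intensity trend Saa3 and Cyp4a14, with array weights Saa3, Rac2 and Cxcl16, with replicate number as a block Saa3 and Cxcl16, and with all arrays quantile-normalized together Saa3. For nano ZnO 10 differed, with 2.51 for A1bg, 2.06 for Slc10a2, 1.41 for Serpinb1a, 1.01 for Gstm6, 0.98 for Ntrk2, 0.94 for Ly6e, 0.93 for Slc39a4, 0.75 for Apoa4, 0.57 for P2ry10b and -1.93 for Cyp2a22. Calls ended for Gstm6 (16 fits, 0.86 to 1.02), P2ry10b (12 fits, 0.52 to 0.58) and Ly6e (9 fits, 0.83 to 0.92), and for Apoa4 without pregnant untreated replicate 5 (0.68). A fit of the compared groups alone ended those of Gstm6, Apoa4 and P2ry10b, replicate number as a block these and that of Ly6e, and that of Gstm6 also ended over all probe sets, after a further quantile normalization and with all arrays quantile-normalized together. Against formulation, the response to micro ZnO differed between the experiments at 53 probe sets, among them Nr4a1, Jun, Btg2, Atf3 and Igfbp1, and that to nano ZnO at 2, Jun and Fos.

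Probe sets without a gene symbol stood outside the comparisons, and some of these 12102 were called when tested alike. There were 1596 in virgin formulation, 177 in virgin micro ZnO and 723 in virgin nano ZnO mice against untreated, 359 for micro ZnO and 178 for nano ZnO against formulation in virgin mice, and 1 in pregnant micro ZnO mice against untreated.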

How the results depend on the processing

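The covariates, the joint quantile normalization and the fit without both pregnant micro ZnO arrays that lay apart were chosen after seeing the data. Counts are of called probe sets unless lists are named. For the changes below the cause was not tested, except that a stricter threshold, fewer arrays or more probe sets tested lower or raise a count by construction.

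Of the values of named genes, the planned settings reversed none. Direction and call were the same for 392 and a call was gained for 2 with dim probe sets left out, the same for 401, lost for 8 and gained for 1 with array weights, the same for 384, lost for 22 and gained for 4 after a further quantile normalization, the same for 375 and lost for 35 over all probe sets, and the same for 370 and lost for 40 in fits of the compared groups alone. They were the same for 382, lost for 26 and gained for 2 with an intensity trend and robust moderation, and the same for 363, lost for 46 and gained for 1 with replicate number as a block. Calls were lost for 81 values with the interquartile range and for 160 with the clock score as a covariate, against 243 and 163 that were the same, and 1 was gained with the interquartile range. Reversed were Slc30a10 in virgin micro ZnO (0.17) and Slc30a1 in virgin nano ZnO (-0.034) with the clock score, and Slc30a1 in pregnant against virgin untreated mice (0.33) with all arrays quantile-normalized together.

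With a change of at least 1.5-fold required, virgin counts were 352 (formulation), 162 (micro ZnO), 244 (nano ZnO), 144 (micro ZnO against formulation) and 68 (nano ZnO against formulation), and that of pregnant against virgin untreated mice was 12461. With the interquartile range as a covariate they were 179, 529, 966, 214 and 156 in the same virgin order, and 4 and 38 for pregnant formulation and micro ZnO. With the clock score as a covariate they were 3975, 2, 3, 225 and 32, and 6 for pregnant formulation. Quantile-normalized again, virgin formulation had 3971 and pregnant nano ZnO against formulation 1. With all arrays quantile-normalized together, pregnant against virgin untreated mice had 7442.

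In fits of the compared groups alone the counts were 189 (virgin nano ZnO against formulation), 53, 8 and 11 (pregnant formulation, micro ZnO and nano ZnO) and 5 (micro ZnO interaction). Over all probe sets they were 6 and 13 for pregnant formulation and micro ZnO and 5 for the micro ZnO interaction. With array weights pregnant formulation had 39 and nano ZnO 13. Without both arrays that lay apart pregnant micro ZnO had 7 and the micro ZnO interaction 6.

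With replicate number as a block the counts were 469 (virgin micro ZnO), 1727 (virgin nano ZnO), 974 and 344 (micro ZnO and nano ZnO against formulation), 8 (pregnant formulation), 11 (formulation interaction) and 6 (nano ZnO interaction). The numbers pair no mice as far as the data show. Residuals of arrays with the same replicate number correlated at a mean of -0.133 over 36 pairs in virgin mice, against 0.0266 for other pairs. There 0 of 24 arrays were closest to an array of their own number. In pregnant mice the means were 0.0359 over 31 pairs and -0.00719 for other pairs, and 3 of 22 arrays were closest to their own number. In virgin mice arrays of the same number were thus less alike than others, for a reason that was not tested.

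With camera at an estimated correlation the called lists were 0 (virgin formulation), 2 (micro ZnO), 0 (nano ZnO), 1 (micro ZnO against formulation), 0 (nano ZnO against formulation) and 0 (nano ZnO against micro ZnO), in pregnant mice 0, 1, 0, 0, 0 and 0 in the same order, and 11 between the untreated groups. With fry they were 24 for virgin formulation, 0 for virgin nano ZnO against micro ZnO, 1, 2, 1, 1, 0 and 0 in pregnant mice in the same order and 37 between the untreated groups. Camera at its preset correlation had called 15, 13, 15, 16, 10 and 13 lists in virgin mice, 13, 18, 13, 10, 8 and 10 in pregnant mice and 21 between the untreated groups. Over the 500 probe sets with the smallest p in virgin mice the correlation of fold changes between experiments was 0.685 for formulation minus untreated, 0.776 for micro ZnO and 0.772 for nano ZnO, over probe sets chosen by their p and not set against permuted labels.

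Leaving out 1 array at a time, virgin counts ran from 4344 to 6772 (formulation), 531 to 1115 (micro ZnO), 1610 to 3473 (nano ZnO), 847 to 1812 (micro ZnO against formulation), 251 to 1115 (nano ZnO against formulation) and 0 to 0 (nano ZnO against micro ZnO). Pregnant counts ran from 5 to 19, 11 to 138, 4 to 10, 0 to 41, 0 to 1 and 0 to 0 in the same order, interactions from 18 to 43, 5 to 49 and 7 to 11, and the untreated comparison from 21049 to 21268. Lists ran from 14 to 20, 12 to 15, 13 to 17, 13 to 17, 9 to 15 and 11 to 17 in virgin mice, from 12 to 16, 10 to 19, 12 to 18, 9 to 13, 4 to 11 and 7 to 12 in pregnant mice and from 20 to 21 between the untreated groups. The correlation of fold changes ran from 0.482 to 0.558 (formulation), 0.351 to 0.430 (micro ZnO) and 0.477 to 0.568 (nano ZnO).

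What the arrays can show is limited by their number and by signal over background, because dim probe sets compress changes, and the values used came without detection calls. The simulated data with 5 or 6 arrays per group gave calls for most probe sets changed 2-fold. Array medians differ between pregnant and virgin mice, so levels across experiments carry a shift of -0.61 in the median.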

Other observations

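The fits with covariates were chosen after seeing the data. Bile acid genes were higher with micro ZnO than with formulation in virgin mice for 7 of 30 measured members and lower for 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.000307, adjusted p = 0.230 with an estimated correlation). Nr1h4, the bile acid receptor, was higher by 0.49 ± 0.09, Klb, the coreceptor of an intestinal hormone that limits bile acid synthesis, by 0.47 ± 0.10 and Slc10a1, the main importer of bile acids into hepatocytes, by 0.26 ± 0.07. Targets of the drug-sensing receptors CAR and PXR were higher for 8 of 33 and lower for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 5.28e-05, adjusted p = 0.230 with an estimated correlation), with Cyp2c38 at 0.67 ± 0.13. Clock genes were higher for 7 and lower for 1 of 20 in the same contrast (9 and 2 adjusted over the list alone, camera adjusted p = 0.00231, adjusted p = 0.238 with an estimated correlation), with Tef at 0.66 ± 0.14 and Nfil3 at -0.90 ± 0.22. With the clock score as a covariate the calls of Klb (0.29), Slc10a1 (0.21), Cyp2c38 (0.51), Tef (0.22) and Nfil3 (-0.47) ended, and with the interquartile range those of Klb (0.44) and Slc10a1 (0.24).

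Early-response and glucocorticoid-responsive genes were also higher with nano ZnO than in untreated virgin mice. Of 25 immediate early genes 6 rose (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.87e-06, adjusted p = 0.195 with an estimated correlation), with Btg2 at 1.37 ± 0.25 and Atf3 at 1.21 ± 0.24. The mean of that list per array, relative to the mean of the experiment, was 0.22 to 0.41 in nano ZnO replicates 2, 3 and 4. It was -0.28 to -0.08 in replicates 1, 5 and 6, against -0.48 to -0.27 in untreated mice. Of 21 glucocorticoid-responsive genes 8 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 7.89e-06, adjusted p = 0.156 with an estimated correlation), with Dusp1 at 1.76 ± 0.30. With the clock score as a covariate the calls of Btg2 (1.92), Atf3 (1.25) and Dusp1 (1.62) ended.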
